A study of Homo sapiens with 6 samples.

How the data were processed

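RNA sequencing was carried out on 6 samples of SCC25, an established human cell line from a squamous cell carcinoma of the tongue. The labels put 3 samples in a control group and 3 in a group with a short hairpin against LIS1, the protein encoded by PAFAH1B1, named shLIS1 here. The labels number the hairpin samples 1 to 3 without saying whether these were replicates of 1 hairpin or separate hairpins, and they do not say whether the control cells carried a hairpin. The design text speaks of a hairpin knockout. A short hairpin lowers a transcript and does not remove the gene, so the level of PAFAH1B1 was reported for every library. Per the labels' protocols, RNA was extracted with Trizol, polyadenylated RNA was captured on oligo(dT) beads, and strand-marked libraries were made with dUTP in the second strand. All 6 samples carry batch 1 in the labels.

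The deposited table holds raw read counts per gene, whole numbers that were not normalized by the authors, for 26524 genes in the 6 libraries, with gene identifiers, symbols, and coordinates. The submitters' processing notes name build hg 38. The aligner, the counting tool, the annotation release and the strand setting of the counting are not given in the sources used here. Genes that share sequence with a near-identical copy, overlapping genes and antisense pairs are therefore uncertain. For 6541 genes the identifier stands in place of a symbol, and 0 genes had no count in every library.

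Counts were tested with edgeR 4.0.16 in R 4.3.3, after filterByExpr (minimum count 10, minimum total count 15) and TMM scaling, with the quasi-likelihood test (glmQLFit with robust=TRUE, glmQLFTest) on group alone. P-values were adjusted by Benjamini-Hochberg over the 14964 genes that passed the filter, and an adjusted p below 0.05 was the threshold. Standard errors were obtained as the absolute log2 fold change over the square root of the F statistic. Levels are given as counts scaled to TMM library sizes (CPM), as mean ± SD of 3 libraries. A count of 0 allows up to 3 counts, which was between 0.132 and 0.192 CPM in the 6 libraries, and such floors cover counting error only.

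Before the data were examined, 33 gene lists, the alternatives and the rule for named genes were fixed. The lists covered serine and folate metabolism, ATF4 and NRF2 targets, sterol and fatty acid synthesis, respiration, ribosomes, lysosomes, keratinocyte and mesenchymal identity, nerve contact, proteases, cell cycle, p53 and YAP targets, interferon and NF-kB targets, stress responses, dynein, and markers of other cell types. Lists were tested with camera of limma 3.58.1 with an inter-gene correlation of 0.01, PAFAH1B1 left out, where at least 3 members were tested. The genes named were PAFAH1B1, 5 serine synthesis genes, the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, the 3 most significant rises and falls, and up to 2 members that rose and 2 that fell with the smallest p in each list. Genes outside this rule are said to have been chosen after their values were seen. Of the genes that the rule names, 1 is left out of the text. The theme of serine metabolism is named in the series title and was not chosen independently of these samples.

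The alternatives were RLE and upper quartile scaling, no filter on low counts, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the quasi-likelihood fit without robust estimation, the replicate number as a block, leaving out each library in turn, camera with a correlation estimated from the data, and fry. Another alternative was chosen after the data were seen. In it, the deviation of each library from the mean library was smoothed over log2 transcript length and GC content with mgcv 1.9.3 (basis size 6 per axis) and entered edgeR as an offset. Camera with an estimated correlation was also run with this offset. That form of camera takes its degrees of freedom from the few libraries, not from the many genes. Small p-values are therefore hard to reach with it at any correlation. Length and GC content came from the longest transcript per gene in GENCODE release 29, preferring protein-coding transcripts. They were found for 14491 genes, 96.8% of those tested.

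The test was checked on simulated counts for 14964 genes with the library sizes, means and dispersion of these libraries. Of 50 genes changed 1.25-fold, 36% were recovered, and recovery was 70% at 1.5-fold, 84% at 2-fold and 96% at 4-fold. Unchanged genes made up 3.38% of the simulated calls. In a simulation of the fitted length and GC trend with no changed gene, edgeR called 28.5% of 14283 genes without the offset and 0% with it. The simulated trend came from the same smooth as the offset, so the 0% holds for a trend of that form only.

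Replicate libraries were compared before averaging. The chi-square per gene was between 2.52 and 10.3 for pairs within a group and between 37.0 and 48.5 for pairs across groups, so no pair differed by sampling noise alone. The labels do not state that the samples came from separate cultures, so the p-values measure the spread between these samples, which may be technical.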

Results

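The transcriptome of SCC25 cells was measured by sequencing of polyadenylated RNA in 3 control libraries and 3 shLIS1 libraries. Total counts were 15661916, 20257902 and 20549728 in control libraries 1 to 3 and 21537087, 17674881 and 22790599 in shLIS1 libraries 1 to 3. The single comparison of the design, shLIS1 against control, addresses which transcripts change when LIS1, a regulator of the dynein motor, is lowered. The series title links LIS1 to serine metabolism and to perineural invasion, the growth of tumour cells along nerves. The first principal component held 60.1% of the variance and separated the groups. The second held 14.5% and set control library 1, at 27.1, apart from control libraries 2 and 3, at -16.4 and -14.1.

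PAFAH1B1 (ENSG00000007168, chromosome 17, 2593210 to 2685615, plus strand, build hg 38) was lower in all 3 shLIS1 libraries. Its level was 157, 165 and 154 CPM in control libraries 1 to 3 and 111, 109 and 113 CPM in shLIS1 libraries 1 to 3. The mean fell from 159 ± 5.56 CPM to 111 ± 2.17 CPM (SD, n = 3 each), which left 69.8% of the control level. The log2 fold change was -0.52 (SE 0.05, edgeR adjusted p = 6.5e-08). With an offset over transcript length and GC content, chosen after the data were seen, 56.9% was left (log2 fold change -0.81).

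The serine synthesis genes fell together. PHGDH (ENSG00000092621, chromosome 1, 119648411 to 119744218), which catalyses the first step from 3-phosphoglycerate, fell from 269 ± 7.32 to 110 ± 3.43 CPM (SD, n = 3 each), a log2 fold change of -1.29 (SE 0.05, edgeR adjusted p = 5.1e-13). PSAT1 and PSPH, the next enzymes of the pathway, had log2 fold changes of -0.63 and -0.49. SHMT1 and SHMT2, which interconvert serine and glycine, had log2 fold changes of -0.55 and -0.58. All 5 genes passed the threshold, with the same 5 adjusted over the list alone, and the median log2 fold change was -0.58. Camera called the list lower (adjusted p = 4.6e-08), with adjusted p = 0.287 with an estimated correlation. Here and for the lists that follow, counts adjusted over the list alone were the same where none is given. This list follows the series title and is not independent evidence of its direction.

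**Figure D1:**
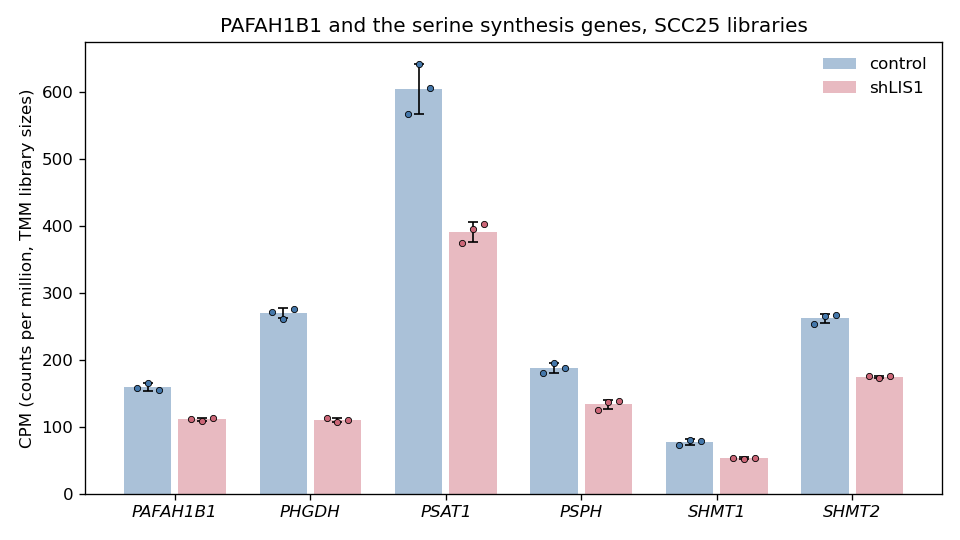
CPM of PAFAH1B1 and 5 serine synthesis genes, with bars for the mean of 3 libraries per group, error bars for the SD and points for single libraries. For each gene the 3 shLIS1 libraries lie under the 3 control libraries, as for PHGDH at 110 against 269 CPM.

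In the wider list of serine, glycine, folate and transsulfuration genes, 21 of 37 tested genes fell, 7 rose and 9 did not pass, with the same counts adjusted over the list alone. The 2 rises with the smallest p were the neutral amino acid transporters SLC38A2 (log2 fold change 0.62) and SLC38A1 (0.55). CBS, which starts transsulfuration, fell with a log2 fold change of -2.18 (SE 0.52, adjusted p = 0.028), from control levels of 13.1, 36.4 and 37.3 CPM. The CBS call was lost in 9 of the alternatives, with an edgeR or limma adjusted p of up to 0.111. Leaving out any library other than control library 1 ended it, with adjusted p from 0.0841 to 0.104. CBS has a near-identical copy, CBSL, so reads may be shared. Camera called the list lower (adjusted p = 0.00012), with adjusted p = 0.338 with an estimated correlation.

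Of 36 tested targets of ATF4, the transcription factor of the amino acid response, 23 fell, 7 rose and 6 did not pass, and the counts adjusted over the list alone were the same. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, fell with a log2 fold change of -1.03, while VEGFA rose with 0.57. The list shared 9 members with the serine and folate list. Camera called it lower (adjusted p = 5.1e-07), with adjusted p = 0.287 with an estimated correlation. Among 20 cytosolic aminoacyl-tRNA synthetases, 9 fell, including SARS1 and AARS1 (both -0.50), 3 rose, including RARS1 (0.31), and 8 did not pass, with the same counts adjusted over the list alone. That list was not called (camera adjusted p = 0.083), and it was called without control library 1 (adjusted p = 0.011).

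Across all genes, 3518 were higher and 3731 lower in shLIS1 among the 14964 tested, and 8102 had an unadjusted p below 0.05. At least 2-fold changes were seen for 511 higher and 176 lower genes, against 317 and 127 with an offset over length and GC content, and 393 and 110 with a filter of at least 1 CPM in 3 libraries. With upper quartile scaling 3146 were higher and 4214 lower. The groups did not overlap for 56.1% of tested genes, against 10% by chance for 3 against 3. Among genes with a mean of at least 5 CPM and no overlap between groups, the largest rise was A2ML1, a protease inhibitor of stratified epithelia, with a log2 fold change of 2.84 (SE 0.16, edgeR adjusted p = 5.4e-11), from 1.73 ± 0.0109 to 12.4 ± 2.02 CPM (SD, n = 3 each). It was followed by SPRR2E (2.45), CEACAM6 (2.42), ZNF117 (2.21), SERPINB2 (2.17), GOLGA8A (2.16), CFAP44 (2.09), SPRR1A (2.02), AKAP9 (1.96), INHBA (1.86), SPRR2D (1.75) and BRCA2 (1.70). SPRR2E, SPRR2D, GOLGA8A and ZNF117 belong to families of similar genes, so their counts are uncertain. INHBA, the activin A subunit, CCNL1 (1.69) and GOLGB1 (1.45) were the most significant rises.

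Among genes under the same conditions, the largest fall was ABCG1, a cholesterol exporter, from 25.1 ± 1.85 to 3.03 ± 0.570 CPM (SD, n = 3 each), with a log2 fold change of -3.03 (SE 0.13, edgeR adjusted p = 5.5e-13). After CBS came PADI3 (-2.05), the neurotrophin receptor NGFR (-2.05), the cholesterol exporter ABCA1 (-1.85), RAB26 (-1.79), LYPD1 (-1.74), SEMA6B (-1.63), PPP2R2B (-1.50), ZSCAN31 (-1.50), TENT5B (-1.34) and TEF (-1.31). PHGDH, ABCG1 and ASS1, which makes argininosuccinate (-1.06), were the most significant falls.

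The fold changes followed the composition of the transcripts. The median log2 fold change was 0.28 in the quintile of genes with the lowest GC content and -0.28 in the quintile with the highest. It was -0.19 in the quintile of the shortest transcripts and 0.18 in that of the longest. Across 14491 genes, which are not independent replicates, Spearman's rho was -0.501 with GC content and 0.292 with length. With an offset over length and GC content, chosen after the trend was seen, 2569 genes were higher and 3485 lower. Of 7125 genes that were called without the offset and also tested with it, 4276 kept their call and direction and 141 were called in the opposite direction. Among the 130 genes that the rule names, all of which passed, 118 kept their call, 0 were called in the opposite direction and 12 lost it. CBS stayed nearly as large, from -2.18 to -1.95 (adjusted p = 0.051). ADAM10 went from 0.53 to 0.04, DSC3 from 0.47 to 0.09, LARS1 from 0.33 to 0.05, GPAM from 0.37 to 0.04, P4HB from -0.28 to -0.06, ESAM from -0.45 to -0.19 and H1-2 from -0.30 to -0.18. The other 4 changed sign: JUND from -0.29 to 0.09, ACSL3 from 0.36 to -0.04, ERO1A from 0.29 to -0.08 and SCARB2 from 0.20 to -0.03. The 118 that kept their call had 33.1% to 157% of their log2 fold change with the offset, with a median of 82.9%. In 12 of them less than 50% was left: SLC38A2 (0.26), SLC38A1 (0.19), SEMA3A (0.35), KRT14 (-0.17), ENO1 (-0.15), CTSD (-0.25), TK1 (-0.28), POLD1 (-0.21), KLK5 (-0.24), PSMB8 (-0.18), FDXR (-0.33) and FADS3 (-0.36).

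**Figure D2:**
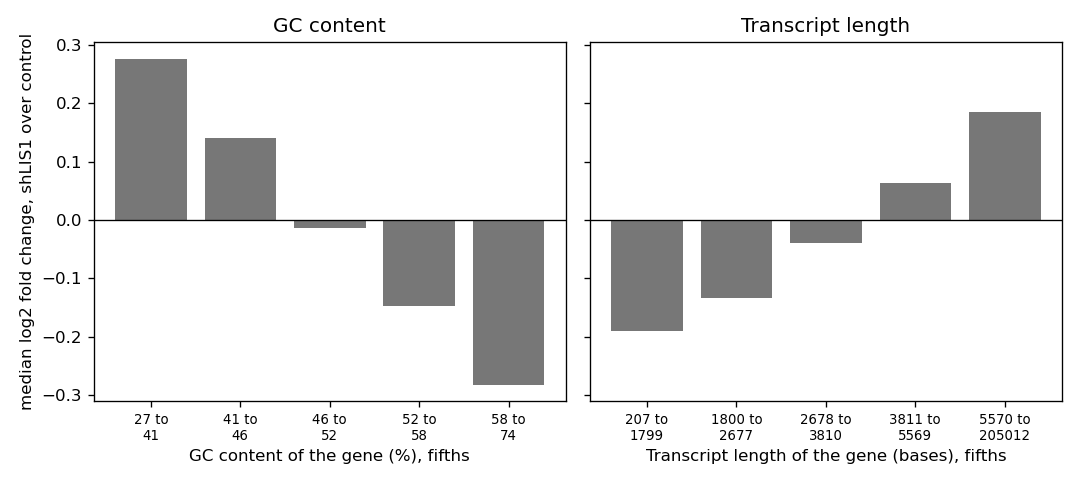
Median log2 fold change of shLIS1 over control (vertical axis) in quintiles of tested genes by GC content (percent, left) and transcript length (bases, right). Bars run from 0.28 to -0.28 with rising GC content and from -0.19 to 0.18 with rising length.

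Genes of the ribosome and of the nuclear-encoded respiratory chain fell. Of 50 cytosolic ribosomal protein genes, 42 fell (43 adjusted over the list alone), 0 rose and 8 did not pass, with RPS2 (-0.80) and RPLP0 (-0.68) as examples. Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain. Of 49 nuclear-encoded respiratory chain genes, 40 fell (41 adjusted over the list alone), 0 rose and 9 did not pass, with COX8A (-0.68) and ATP5F1B (-0.54) as examples. Mitochondrial-encoded genes went the opposite way, with 10 of 13 higher and 0 lower (the same counts adjusted over the list alone), including MT-ND5 (0.80) and MT-ND6 (0.81). With the length and GC offset 8 were higher and 1 lower. MT-ND6 lies directly after MT-ND5 on the other strand, and the strand setting of the counting is not known, so its counts are uncertain. Counts on the mitochondrial genome made up 5.72% ± 0.370 of the control totals and 7.59% ± 0.124 of the shLIS1 totals (SD, n = 3 each). Camera called the ribosomal (adjusted p = 7.8e-12), respiratory (7.8e-12) and mitochondrial-encoded (4.0e-06) lists, and the adjusted p values were 0.338, 0.287 and 0.338 with an estimated correlation.

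Cholesterol synthesis genes rose while SREBF1 fell. Of 26 cholesterol synthesis and SREBP2 target genes, 16 rose (19 adjusted over the list alone), 1 fell and 9 did not pass. HMGCS1 rose with a log2 fold change of 1.40 and SQLE with 0.99, and the 1 gene that fell was INSIG1 (-0.30). Camera called the list higher (adjusted p = 3.2e-07), with adjusted p = 0.292 with an estimated correlation. Of 19 fatty acid synthesis genes, 8 fell, including SREBF1 (-1.31) and FADS3 (-0.71), 4 rose, including ACSL3 (0.36), and 7 did not pass, with the same counts adjusted over the list alone. That list was not called (camera adjusted p = 0.087), and it was called without control library 1 (adjusted p = 0.042).

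Of 32 NRF2 target and glutathione genes, 21 fell, 5 rose and 6 did not pass, with the same counts adjusted over the list alone. The ferritin chains FTL (-0.76) and FTH1 (-0.66) fell, while HMOX1 (0.88), which degrades haem, and the exporter ABCC3 (0.95) rose. The rises were 2 to 5 on leaving out 1 library and 2 with the offset. Of 43 lysosome and autophagy genes, 23 fell (25 adjusted over the list alone), including the proteases CTSB (-0.70) and CTSD (-0.60), 4 rose, including ATG16L1 (0.20), and 16 did not pass. The lysosome rises were 1 to 3 on leaving out 1 library, and the ATG16L1 call was lost without control library 1 and without shLIS1 library 1 or 3. Of 21 heat shock genes, 12 fell, including HSPB1 (-0.81) and HSPB8, and 5 rose, including HSP90AA1 (0.36), with the same counts adjusted over the list alone. Camera called the NRF2 (adjusted p = 0.00033), lysosome (0.0014) and heat shock (0.021) lists lower, and the adjusted p values were 0.292, 0.338 and 0.419 with an estimated correlation. Of 27 endoplasmic reticulum chaperone and unfolded protein response genes, 14 fell, including XBP1 (-0.38), 4 rose, including HSP90B1 (0.58), and 9 did not pass. The list was not called (camera adjusted p = 0.137).

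**Figure D3:**
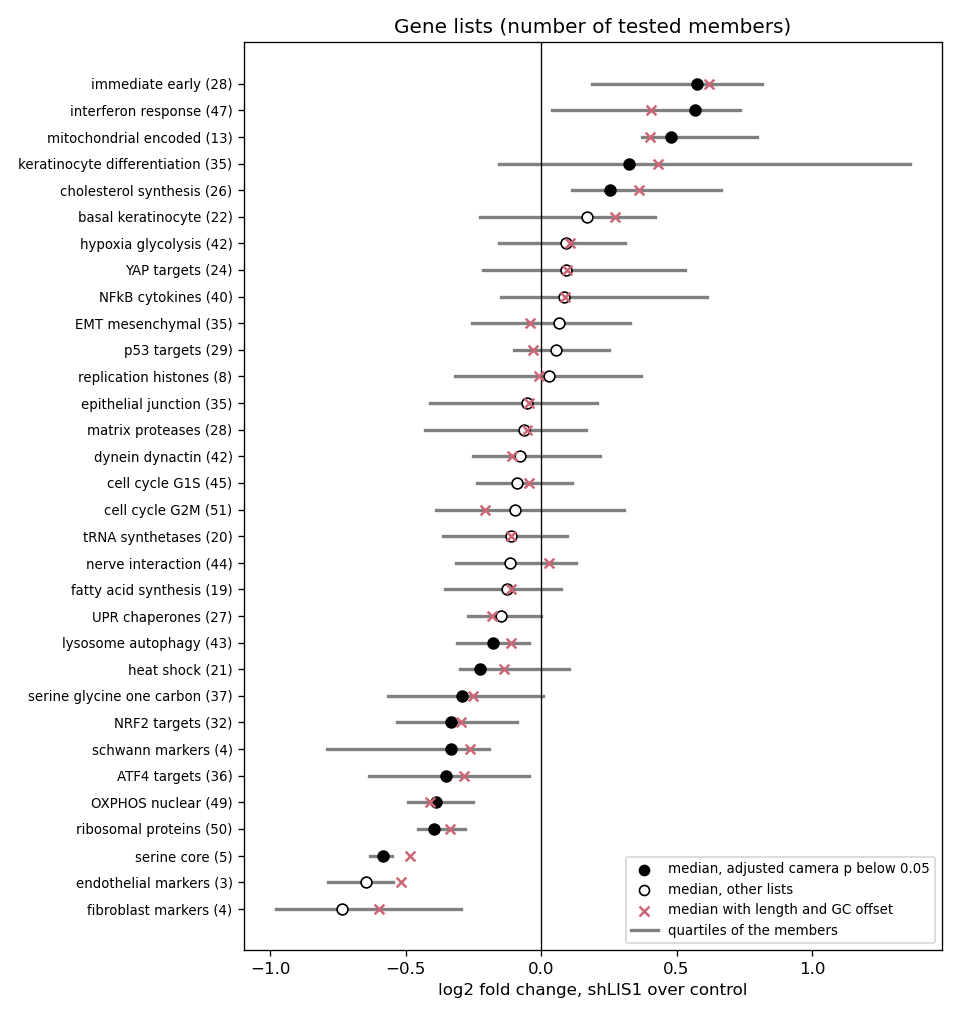
Median log2 fold change of shLIS1 over control (horizontal axis) of 32 gene lists, with the quartiles of their members as grey lines and the number of tested members in brackets. Filled points are the 14 lists called by camera, open points the others, and crosses the medians with the length and GC offset.

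Keratinocyte differentiation genes rose on balance. Of 35 keratinocyte differentiation genes, 18 rose (19 adjusted over the list alone), 7 fell (8 adjusted over the list alone) and 10 did not pass. Involucrin, IVL, rose with a log2 fold change of 2.37, from a low level of 1.42 ± 0.166 to 7.30 ± 1.43 CPM (SD, n = 3 each). SPRR2D, whose counts are uncertain because of similar genes, rose with 1.75, while KRT80 (-0.40) and the protease KLK5 (-0.53) fell. Camera called the list higher (adjusted p = 0.0014), with adjusted p = 0.438 with an estimated correlation. Of 22 basal keratinocyte genes, 11 rose (12 adjusted over the list alone), including DST (1.56), 7 fell, including KRT14 (-0.50) and KRT15 (-0.79), and 4 did not pass. Of 35 epithelial junction genes, 16 fell, including KRT8 (-0.67) and ELF3 (-0.88), 9 rose, including DSP (0.49), and 10 did not pass. Neither of these was called by camera (adjusted p = 0.316 and 0.130).

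Mesenchymal genes and proteases changed in both directions. Of 35 mesenchymal genes, 12 rose (13 adjusted over the list alone), including INHBA, 11 fell, including SPARC (-0.76) and PDPN (-0.64), and 12 did not pass. Of 28 matrix protease genes and inhibitors, 10 fell (11 adjusted over the list alone), including CTSB and MMP7 (-0.90), 7 rose (8 adjusted over the list alone), including MMP10 (1.56), and 11 did not pass. Of 44 genes linked to contact with nerves, 18 fell, 8 rose and 18 did not pass, with the same counts adjusted over the list alone. NGFR and the chemokine CCL2 (-1.04) fell, while SEMA3A (0.85) and EFNB2 (0.72), which guide axons, rose. Camera called none of the mesenchymal (adjusted p = 0.387), protease lists, nor the nerve list (adjusted p = 0.063). The nerve list was called lower without control library 1 (adjusted p = 0.031), without control library 2 (0.024) and with no filter on low counts (0.014), and its median was 0.03 with the length and GC offset.

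Interferon-stimulated genes rose. Of 47 tested, 34 rose, 9 fell (10 adjusted over the list alone) and 4 did not pass. The RNA sensor IFIH1 rose with a log2 fold change of 0.89 and PARP14 with 0.88, while the immunoproteasome subunits PSMB9 (-0.66) and PSMB8 (-0.40) fell. Camera called the list higher (adjusted p = 1.5e-09), with adjusted p = 0.355 with an estimated correlation. Of 28 immediate early genes, 20 rose (21 adjusted over the list alone), including KLF6 (1.19) and DUSP6 (1.15), 1 fell (JUND, -0.29) and 7 did not pass. Camera called that list higher (adjusted p = 4.6e-08), with adjusted p = 0.338 with an estimated correlation. Of 40 NF-kB targets and cytokines, 14 rose, including TNFAIP3 (0.83) and CSF2 (1.45), 10 fell, including CCL2 and TNFRSF9 (-1.22), and 16 did not pass. The list was not called (camera adjusted p = 0.130).

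Cell cycle genes moved both ways without the length and GC offset. Of 51 mitotic genes, 23 fell (24 adjusted over the list alone), including PTTG1 (-0.64) and PLK1 (-0.57), 17 rose, including CENPF (1.15) and CENPE (1.42), and 11 did not pass. With the offset 30 fell and 9 rose, the median was -0.21, and camera called the list lower (adjusted p = 0.011), with adjusted p = 0.546 with an estimated correlation. Of 45 replication and S phase genes, 18 fell, including TK1 (-0.64), 9 rose, including BRIP1 (0.85), and 18 did not pass. Of 29 p53 targets, 7 rose, including FBXW7 (0.87), 4 fell, including PHLDA3 (-0.64), and 18 did not pass. Of 24 YAP targets, 10 rose, including NT5E (0.85), 4 fell, including IGFBP3 (-0.45), and 10 did not pass. Of 42 hypoxia and glycolysis genes, 14 rose (15 adjusted over the list alone), including KDM3A (0.86), 10 fell, including GAPDH (-0.65) and ENO1 (-0.41), and 18 did not pass. Camera called none of these 5 lists in the fit to all libraries with the filter and without the offset, with adjusted p from 0.138 for YAP targets to 0.713 for p53 targets. The YAP list was called higher with no filter on low counts (adjusted p = 0.048) and the hypoxia list without shLIS1 library 1 (0.0497).

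Of 42 dynein, dynactin and adaptor genes, the machinery that LIS1 regulates, 16 fell, 12 rose and 14 did not pass, with the same counts adjusted over the list alone. NIN (0.89) and CLIP1 (0.64) rose, and DCTN2 (-0.54) and DYNLT1 (-0.44) fell. The list was not called (camera adjusted p = 0.713).

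Few markers of other cell types passed the filter on low counts. Of 4 tested fibroblast markers, 3 fell, including COL1A1 from 12.8 ± 1.87 to 8.98 ± 0.701 CPM (SD, n = 3 each) and COL1A2 (-0.97), and the list was not called (camera adjusted p = 0.309). Of 4 tested Schwann cell markers, 3 fell, including NGFR and MBP (-0.37), which had control means of 70.4 and 54.7 CPM. Camera called that list lower (adjusted p = 0.0097), with adjusted p = 0.338 with an estimated correlation. SCC25 is a cell line, so the call of these 4 genes is not a measure of Schwann cells, and NGFR is also in the nerve list. Of 3 tested endothelial markers, 2 fell, CDH5 (-0.93) and ESAM (-0.45), and the list was not called (camera adjusted p = 0.083). The leukocyte list had under 3 tested genes and was not tested. Of 8 tested replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 2 rose (1 adjusted over the list alone), H2BC4 (0.52) and H2BC8 (0.72), and 1 fell, H1-2 (-0.30), and the list was not called (camera adjusted p = 0.940). The H2BC8 call was lost on leaving out any 1 library and the H2BC4 call without shLIS1 library 1.

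Some of the smaller counts per list moved by more than 1.5 times with 1 library left out or with the offset. Leaving out 1 library gave 4 to 8 falls of keratinocyte differentiation genes, 5 to 10 of interferon-stimulated genes and 6 to 10 of NF-kB targets, and 3 to 6 rises of heat shock genes and 0 to 2 of histone genes. It gave 1 to 2 falls of cholesterol, immediate early and histone genes, and 0 to 1 rises of respiratory chain genes and Schwann cell markers. With the offset there were 4 rises of ATF4 targets, 1 of tRNA synthetases, 1 of unfolded protein response genes, 3 of heat shock genes and 2 of fatty acid genes. There were 4 falls of keratinocyte differentiation genes, 5 of interferon-stimulated genes, 6 of hypoxia genes, 0 of immediate early and histone genes, and 1 each of mitochondrial-encoded genes and endothelial markers.

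In all, camera called 14 of 32 lists, 5 higher and 9 lower. With an estimated correlation 0 were called, the smallest adjusted p was 0.287, and 5 had an unadjusted p below 0.05, while fry called 26. Camera also called 14 lists in 2 of the other splits of the 6 libraries. Those splits mix the groups unevenly and keep part of the group difference between the sides. The number of called lists was thus not larger in the real grouping, but this comparison cannot tell how many lists would be called without a group difference. With no filter on low counts camera called 19 lists: the same 14, and the tRNA synthetase, nerve, epithelial junction, fatty acid and YAP lists. With the length and GC offset it called 21 lists. These were the same 14, the tRNA synthetase, mitotic, unfolded protein and fatty acid lists as lower, and the basal keratinocyte, NF-kB and hypoxia lists as higher. With the offset and an estimated correlation 0 were called. The NF-kB list with the offset had an estimated correlation of -0.011, under the preset 0.01. Its camera adjusted p still went from 0.0083 to 0.176. The loss of a call with an estimated correlation therefore does not tell whether the members of a list moved together.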

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

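The length and GC offset, alone or with an estimated correlation, was chosen after the data were seen, and the other alternatives were fixed before. PAFAH1B1 and the serine synthesis median stayed lower and past the threshold under every alternative with a test, at -0.81 to -0.48 and -0.62 to -0.48. The exception was camera with an estimated correlation, which did not call the serine list (adjusted p = 0.287), and DESeq2 and limma-voom gave it no list test. At least 2-fold falls numbered 110 with at least 1 CPM in 3 libraries, where fewer genes were tested, against 176. At least 2-fold rises numbered 317 with the length and GC offset, against 511. Camera with an estimated correlation called 0 lists, also with the length and GC offset, and fry 26, against 14. Fry asks another question, whether members move on balance 1 way at all, while camera sets them against the other genes. The count of fry is therefore not comparable. For 142 genes (129 that the rule names besides PAFAH1B1 and 13 chosen after their values were seen) under the alternatives fixed before, 1956 of 1988 values kept direction and side of the threshold, and 30, of CBS, APOE, ATG16L1, H2BC4 and H2BC8, fell short of it. SRSF3, not called, turned from 0.04 to -0.0017 with upper quartile scaling and ran from -0.024 (without control library 1) to 0.092 on leaving out 1 library. With the length and GC offset 128 of the 142 held, 9 fell short and 5 turned: ACSL3 (-0.040), ERO1A (-0.080), JUND (0.088), SCARB2 (-0.033) and SRSF3 (-0.26, called). The cause was not tested beyond the removal of the trend. Leaving out 1 library gave 3011 to 3615 higher and 3034 to 3733 lower genes, and 14 to 17 lists. The 14 lists stayed called, in the same direction, under every alternative run with camera at the preset correlation. Upper quartile scaling gave 3146 higher and 4214 lower genes, with a median log2 fold change of -0.05 over all genes. The replicate numbers did not pair the samples: deviations correlated at -0.038, 0.032 and -0.037, and only number 2 correlated best with its own number. With the replicate block, 3484 genes were higher and 3682 lower, and 15 lists were called, the nerve list (adjusted p = 0.041) added. With no filter 19 lists were called. At the depth, spread and 3 libraries per group of these data, 36% of genes with the smallest simulated change were recovered, and depth was not varied.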

Other observations

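Several transcripts outside the rule for named genes moved by a factor near 2 or more and were chosen after their values were seen. TFRC, the transferrin receptor, rose from 629 ± 62.9 to 1484 ± 5.15 CPM (log2 fold change 1.24), while the ferritin chains FTL and FTH1 fell. HBEGF, a ligand of the epidermal growth factor receptor, rose from 53.1 ± 3.08 to 125 ± 7.99 CPM (1.23), beside the rise of DUSP6. The cytosolic RNA sensor RIGI rose from 0.912 ± 0.210 to 3.92 ± 0.746 CPM (2.12). NEAT1, a nuclear noncoding RNA, rose from 244 ± 41.7 to 785 ± 136 CPM (1.69), and PNISR from 37.9 ± 4.48 to 122 ± 3.54 CPM (1.68). All values are means ± SD with n = 3, and these genes passed the edgeR threshold. The log2 fold changes are without the length and GC offset. With it these genes kept direction and call, and the size of their changes is not given here.

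The tests of the length and GC trend, of single libraries, of the preparation step, of ATF4 and LXR targets and of the hairpin response were chosen after the results were seen. The lists of nuclear and LXR transcripts were also written after their prompting genes were seen, and MALAT1 of the nuclear list had been looked at.

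Long, GC-poor transcripts were higher in shLIS1 and short, GC-rich ones lower. The trend as fitted over length and GC content is argued against as the whole cause of the calls. With the offset that removed it, 6054 genes, 41.8% of those tested, were called. The offset covers only this smooth over the longest transcript of each gene, so other biases of the libraries were not tested. It may still account for part, since in a simulation the trend alone led edgeR to call 28.5% of genes without the offset. Control library 1 alone is argued against, since rho with GC content was -0.447 without it. A preparation step that ran with the group cannot be told apart from the group itself: the correlation per library restates the trend, so its exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows, decides nothing.

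Serine synthesis genes were lower in shLIS1. The length and GC trend as the whole cause is argued against, since all 5 genes were still called lower in edgeR with the offset, with a median of -0.48. The list call with the offset (camera adjusted p = 2.8e-09) was lost with an estimated correlation (adjusted p = 0.176). A fall of abundant transcripts in general as the whole cause is argued against by 10000 random lists matched on expression, length and GC content. Their middle value was -0.16, against -0.58 for the serine genes without the offset, which lay at the 0.0200 percentile. Members of the random lists were drawn independently, while the serine genes had an estimated correlation of 0.28. The percentile therefore overstates how rare the median is and is not a p-value. The list also follows the series title. A lower output of ATF4 targets stays open: the 27 targets outside the serine and folate list had a median of -0.11 with the offset, with 12 lower and 3 higher, and camera p = 0.027 became 0.263 with an estimated correlation. ATF4 itself, at -0.24 before the offset, was at -0.01 with it.

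Interferon-stimulated genes were higher in shLIS1. The length and GC trend as the whole cause is argued against, since with the offset 35 of 47 genes were called higher and 5 lower in edgeR, with a median of 0.40. The list call with the offset (camera adjusted p = 3.9e-15) was lost with an estimated correlation (adjusted p = 0.334). A response to hairpin or vector RNA rather than to lower PAFAH1B1 cannot be told apart from an effect of PAFAH1B1. The labels do not say whether the control cells carried a hairpin, and there were 0 groups with a hairpin against another gene. An effect of lower PAFAH1B1 stays an untested hypothesis for this and the other patterns.

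The fall of ABCG1, ABCA1 and SREBF1, all targets of the sterol receptor LXR, may reflect a lower output of LXR targets. Among 12 other targets the median was -0.15 with the offset, with 5 lower, including MYLIP and PLTP, and 1 higher, APOE, whose call without the offset was lost without control library 2 or 3 and without shLIS1 library 2 or 3. This stays open, since camera in limma did not call the list. The rise of NEAT1, CCNL1 and PNISR may be part of a rise of nuclear and detained-intron transcripts. Among 19 other such transcripts the median was 0.37 with the offset, with 14 higher, including SRSF5 and LUC7L3, and 2 lower, CLK3 and SRSF3. Camera in limma gave that list p = 5.5e-08, or p = 0.017 with an estimated correlation.

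The 6 libraries can be split in 10 ways, too few for a share under 0.05. Every split but the real one has libraries of both groups on each side. The group difference then enters the spread within a side, which by itself keeps the gene calls low. Part of that difference also stays between the sides, from which camera can still call lists. The other splits therefore do not show what libraries without a group difference would give, and the counts that follow decide nothing about chance. The real split called 7249 genes, and the highest other split called 0 with edgeR (97 to 222 genes at an unadjusted p below 0.05 in the other splits), so 1 of the 10 splits gave as many. For changes of at least 2-fold the real split called 687 and the highest other 0, again 1 of 10 splits. Camera called 14 lists in the real split and 14 in the highest other, so 3 of 10 splits gave as many. In both of the others that did, control library 1 was grouped with 2 shLIS1 libraries.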
